A study of Homo sapiens with 2 samples.

How the data were processed

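The series holds 2 arrays of MeWo cells, an established human melanoma line. Cells stably transfected with an IMP-3 expression plasmid (pCMV-IMP3) were compared with cells that carried the empty vector, and both had been selected with puromycin, per the labels' protocols. IMP-3 is the RNA-binding protein encoded by IGF2BP3. On each array the RNA of IMP-3 cells carried Cy5 and that of vector cells Cy3. Both arrays ran in this 1 orientation, so a dye effect of a gene and an effect of the plasmid cannot be separated. The labels call the 2 arrays biological replicates but do not say whether these were separate cultures or separate stable clones, so the p-values measure the spread between these 2 arrays.

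The scanner files hold spot intensity values, that is mean pixel intensities and median local backgrounds per channel, which Agilent Feature Extraction 10.5.1.1 extracted under protocol GE2-v5_95_Feb07 for array design 014850, per the file headers. The same software made processed signals, whose log10 ratio of Cy5 over Cy3 is given per spot per the file headers, together with an error-model p-value of that ratio, which covers 1 array and no biological spread. Other columns hold marks for spots well above background, saturated spots and outliers, per the file headers. The deposited value table of the series holds log2 ratios with medians of −0.006 on array 1 and −0.012 on array 2. For 100% of the 40736 probes with a single spot these equalled the log2 ratio of the processed signals of the same array, Cy5 over Cy3, to within 0.001, which settles scale and direction. They equalled the scanner's own log ratio for 97.1% and 92.1% of those probes, and the others were given as 0 by the scanner software. How the submitters went from the processed signals to that table is not given in the sources used here.

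From the intensities, each channel was background-corrected with normexp (offset 50) and each array was normalised by loess in limma 3.58.1 under R 4.3.3. Control spots and spots marked as outliers (111 on array 1 and 367 on array 2) had weight 0 in the loess curve and were left out afterwards. Spots of the same probe were averaged. A probe was kept if it was well above background in at least 1 channel on each of the 2 arrays, which left 33039 of 41000 probes. Probes took current gene symbols from a RefSeq table of assembly GRCh38.p14, used for names only. Of all probes, 26386 were matched by accession, 2399 by symbol and 596 by an older symbol, 1034 kept the name in the file and 10585 stayed unnamed. A gene was represented by its kept probe with the highest mean log2 intensity over both arrays, chosen without regard to the ratio, which gave 16829 genes. Probe coordinates are those in the files, on hg19 (GRCh37).

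The log2 ratio of Cy5 over Cy3 of each kept probe was tested against 0 with limma (lmFit with an intercept, then eBayes), with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. The 2 RNAs of a pair shared an array, so the ratio pairs them, and that pairing comes from the hybridisation itself. An exact sign-flip test on 2 arrays cannot go below p = 0.5, so the number of genes with ratios of at least 2-fold in 1 direction on both arrays is given beside the test. Channel intensities of single RNAs come from the loess-normalised values after Aquantile scaling of the arrays. A gene not well above background in 1 of the groups on both arrays is given as a lower bound of its fold, which is open to dye bias. Each array had its own slide and scan, and each held both groups, so the values of a single array are also the values within a batch.

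The 32 gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule names IGF2BP1, IGF2BP2, IGF2BP3 and HMGA2 always. It then names up to 13 genes per direction, by the size of the mean log2 ratio, among genes past the test. Where too few pass, genes with ratios of at least 2-fold in 1 direction on both arrays fill the places, without clone-type or placeholder names. From each list it names the 2 members with the largest mean log2 ratio in size where none pass. Some genes are not reported by name.

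Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation, fry, and the percentile of a list's median among 10000 random lists of matched intensity stood beside it. The lists covered the IMP family, reported IMP-3 target mRNAs, let-7 target mRNAs, pigmentation, undifferentiated melanoma, mesenchymal transition, epithelial adhesion, extracellular proteases, collagens and matrix, the insulin-like growth factor axis, mitosis, DNA replication and p53 targets. They also covered interferon-stimulated genes, antigen presentation, NF-kB targets, immediate early genes, MAPK feedback, the unfolded protein response, heat shock, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, histones, cancer-testis antigens and RNA-binding partners. Markers of keratinocytes, fibroblasts, leukocytes, endothelium and the nervous system completed them.

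The procedure was tested on simulated data, 5 sets of ratios for the 33039 probes with 200 changed probes each. The spread of each probe was drawn from the real fit. Spread and change of a probe were the same on both simulated arrays. Of probes changed 2-fold the procedure recovered 0%, of those changed 4-fold 32.8%, of those changed 8-fold 83.2% and of those changed 16-fold 91.6%. It also called 36 unchanged probes over the 5 sets. Real ratios were wider on array 2 than on array 1, so these shares do not give the power for the real genes. Camera at the preset correlation called 20 of 20 simulated lists shifted by 0.5 (log2) and 0 of 80 unshifted ones, and with an estimated correlation 0 of the 20. A lack of calls with an estimated correlation therefore does not speak against a shift. When the members of unshifted lists shared a deviation (SD 0.3) on each array, camera at the preset correlation called 66 of 100.

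Alternatives were no background correction, a normexp offset of 16, the scanner's processed signals, median centring in place of loess, scale normalisation between arrays, no filter on dim probes, a filter on both channels, an intensity trend with robust eBayes, both channels as 4 samples with no pairing, the deposited value table, each array alone, 1.5-fold in place of 2-fold, the scanner's p under 0.01 on both arrays, and every probe on its own. The mean of all kept probes of a gene was added after seeing the data. Files were read with data.table, version 1.17.8, and sequences with Biostrings 2.70.1, and plots were drawn with matplotlib 3.10.9 and pandas 2.3.3. The number of arrays limits the precision.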

Results

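Gene expression was measured on 2 two-colour oligonucleotide arrays, each of which paired RNA of MeWo melanoma cells carrying an IMP-3 expression plasmid (Cy5) with RNA of MeWo cells carrying the empty vector (Cy3). The median spot signal on array 1 was 254 in the vector channel and 424 in the IMP-3 channel, over median backgrounds of 26.5 and 49. On array 2 these signals were 169 and 283, over backgrounds of 23 and 51. Probes well above background made up 85.9% (vector) and 91.5% (IMP-3) on array 1, and 77.9% and 79.6% on array 2, and 0 spots were saturated. Among 251 probes with at least 5 spots, the log2 ratios of spots of the same probe had a pooled SD of 0.05 on array 1 and 0.06 on array 2.

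The comparison asks which transcripts differ in abundance between melanoma cells that carry the IMP-3 plasmid and vector cells. Among genes named by the rule, with ratios of at least 2-fold on both arrays, the highest mean ratios belonged to SLITRK6, which encodes a neuronal transmembrane protein, at 7.98-fold (log2 3.0 ± 2.58, SD, n = 2 arrays) and to CCN5, a secreted matricellular protein listed on the array as WISP2, at 5.40-fold (2.43 ± 1.57). They were followed by TGFB2, a transforming growth factor beta ligand, at 4.31-fold (2.11 ± 1.44), the oxysterol receptor GPR183 at 4.11-fold (2.04 ± 1.44) and the matrix proteoglycan LUM at 4.0-fold (2.00 ± 1.23). In the same set the lowest mean ratios belonged to the neurofilament gene NEFM (log2 −3.40 ± 1.65), the IMP paralogue IGF2BP1 (−3.13 ± 2.08), the neuronal ubiquitin hydrolase UCHL1 (−2.81 ± 1.69), the netrin receptor UNC5B (−2.63 ± 1.72) and the transcription factor SOX11 (−2.53 ± 1.72). None of these genes passed the test, since limma with Benjamini-Hochberg adjustment gave 0 genes past an adjusted p of 0.05, and the smallest adjusted p was 0.682.

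At an unadjusted p under 0.05, limma counted 450 genes higher and 373 lower in IMP-3 cells, where chance alone gives 841 among 16829 genes. Genes under that limit, in both directions, depended on the scaling and the pairing. They numbered 2221 with scale normalisation between the arrays and 124 with no pairing of the channels. With median centring, which moved the median of all genes to 0.14, they numbered 3812. Ratios of at least 2-fold in 1 direction on both arrays were found for 11 genes higher and 10 lower in IMP-3 cells, and 0 genes reached 2-fold in opposite directions. With the scanner's processed signals these counts were 48 and 55, from the deposited values 48 and 56, with median centring 50 and 16, and with scale normalisation between the arrays 28 and 16. Of these genes, DHCR7, which catalyses the last step of cholesterol synthesis (1.79 ± 1.02), the transglutaminase TGM2 (1.78 ± 0.91) and the atypical kinase MAPK4 (1.08 ± 0.10) were higher. The growth factor receptor FGFR3 (−2.49 ± 1.84), GOLPH3L (−2.25 ± 1.77), the actin-like gene ACTL8 (−1.81 ± 0.05) and the hexokinase-related HKDC1 (−1.37 ± 0.47) were lower. ACTL8 was well above background in the IMP-3 channel on 1 of the 2 arrays. A second probe of NEFM gave 0.09 and 0.03 on the 2 arrays, one of HKDC1 −0.02 and 0.21, and one of GOLPH3L 0.13 and −1.67. One of TGM2, not well above background in vector RNA on either array, gave −0.02 and 0.96.

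Ratios on array 2 were wider than on array 1. The SD of log2 ratios across genes was 0.19 on array 1 and 0.60 on array 2, and 11 genes higher and 12 lower reached 2-fold on array 1 against 577 and 684 on array 2. SLITRK6 stood at 1.17 on array 1 and 4.82 on array 2, CCN5 at 1.33 and 3.54, TGFB2 at 1.09 and 3.12, NEFM at −2.23 and −4.57, UCHL1 at −1.62 and −4.0, and SOX11 at −1.31 and −3.75. Close values on both arrays were measured for ACTL8 (−1.85 and −1.78) and MAPK4 (1.00 and 1.15). Across genes, which are not independent replicates, the ratios of the 2 arrays correlated at Pearson r = 0.40 and Spearman rho = 0.34, and 61.7% of genes had the same sign on both. Channel intensities across all kept probes correlated at r = 0.997 between vector and IMP-3 RNA of array 1, 0.978 between the RNAs of array 2, 0.978 between the IMP-3 RNAs of both arrays and 0.966 between the vector RNAs. The dye orientation, the same on both arrays, leaves dye effects of single genes in every ratio.

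**Figure D1:**
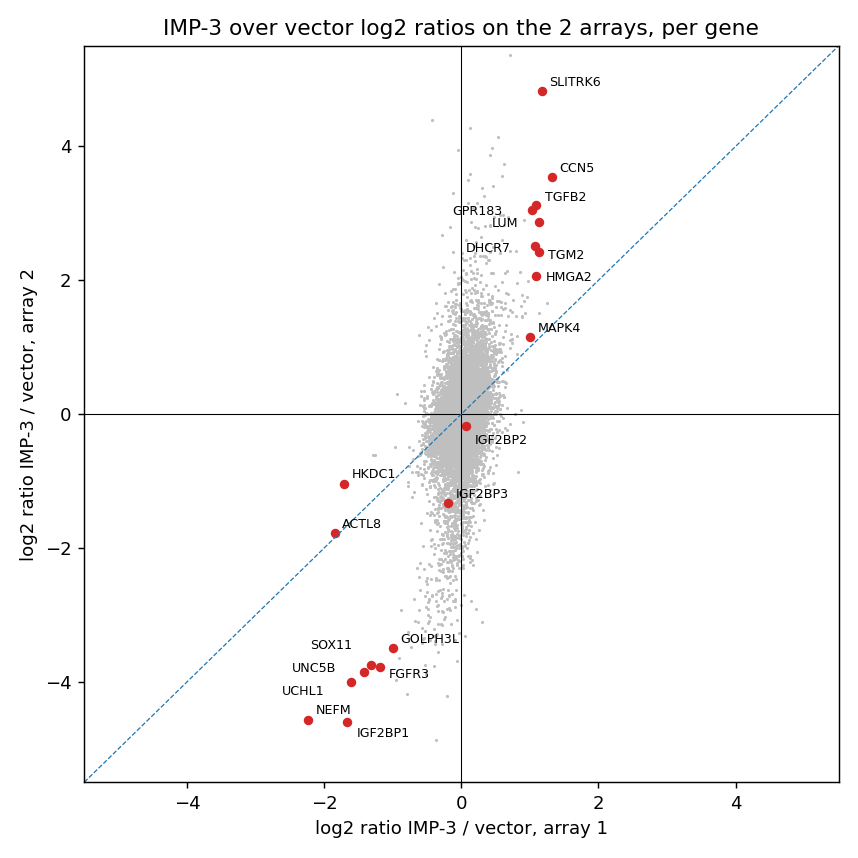
Each point is a gene, with its IMP-3 over vector log2 ratio on array 1 (x axis) and on array 2 (y axis), named genes in red and equal ratios on the dashed line. Most named genes lie farther from 0 on array 2 (SLITRK6 1.17 and 4.82), and ACTL8 lies near the line (−1.85 and −1.78).

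**Figure D2:**
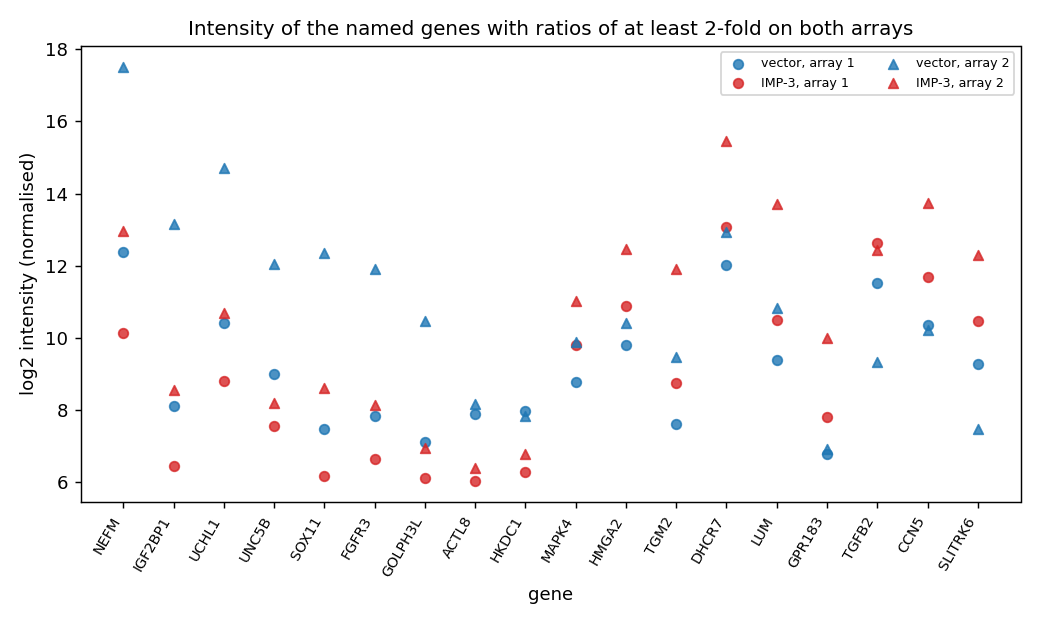
Normalised log2 intensity (y axis) of the named genes with ratios of at least 2-fold on both arrays (x axis), with vector RNA in blue, IMP-3 RNA in red, array 1 as circles and array 2 as triangles. For UCHL1 the vector intensities were 10.42 on array 1 and 14.70 on array 2, and the IMP-3 intensities 8.80 and 10.70.

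IGF2BP3, the gene of the transfected protein, had a log2 ratio of −0.19 on array 1 and −1.33 on array 2 (mean −0.76 ± 0.81, SD, n = 2, limma adjusted p = 0.682). Its probe A_23_P19987 lies on chromosome 7 at 23350769 to 23350828 (hg19), at position 3158 of the transcript and beyond the coding region. The labels do not say whether the plasmid carries that part, so whether the probe can check the transgene is open. These arrays therefore do not show that IMP-3 was overexpressed, and IMP-3 cells here means the RNA labelled as such. Its paralogue IGF2BP1, usually expressed in the embryo, was lower at −1.66 and −4.60 by its probe at chromosome 17, 47132379 to 47132438, and a dimmer probe upstream gave 0.02 and −1.34. IGF2BP2 had ratios of 0.07 and −0.18 (mean −0.05 ± 0.18). Its mean was 0.18 with median centring, which moved the median of all genes to 0.14. The IMP family as a list of 3 had a median of −0.76 (−0.19 on array 1 and −1.33 on array 2), with camera's adjusted p = 0.0549 at the preset correlation and adjusted p = 0.738 with an estimated correlation. At the preset correlation it was called with a normexp offset of 16, processed signals, scale normalisation, no pairing of the channels and the deposited value table.

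HMGA2, an architectural chromatin protein whose mRNA is a reported IMP-3 target, was higher at 1.09 and 2.06 (mean 1.58 ± 0.69, SD, n = 2, limma adjusted p = 0.682) by its brighter probe. That probe, A_23_P95930 (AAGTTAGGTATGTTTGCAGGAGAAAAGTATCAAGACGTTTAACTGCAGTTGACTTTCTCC), lies on chromosome 12 at 66359789 to 66359848 (hg19), at position 3857 of the transcript in the 3′ UTR. The other probe, A_24_P85099 (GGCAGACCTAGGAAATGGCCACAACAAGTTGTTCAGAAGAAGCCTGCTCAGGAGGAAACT), spans an exon junction between 66232332 and 66357033, lies at position 1042 and translates to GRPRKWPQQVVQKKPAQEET of the coding region. It gave −0.02 on array 1 and 0.17 on array 2 (mean 0.08 ± 0.13), and the mean over both probes was 0.83. Of the 14 reported IMP-3 target mRNAs, 5 were higher and 6 lower on both arrays, and LIN28B, an RNA-binding protein that blocks let-7 maturation, stood at −0.49 and −3.01 with its IMP-3 channel well above background on 1 array. The list had a median of 0.05 and a mean of −0.08, and camera gave it the lower direction (adjusted p = 0.965). Among 26 let-7 target mRNAs the median was −0.12 (adjusted p = 0.474), with 7 higher and 12 lower on both arrays, and the zinc finger gene PLAGL1 at −0.07 and −3.68 (−0.03 and −0.52 at a dimmer probe).

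The list of inflammatory cytokines and NF-kB targets had a median log2 ratio of 0.73 over 26 genes (0.17 on array 1 and 1.1 on array 2). Camera called it higher in IMP-3 cells at the preset correlation of 0.01 (adjusted p = 4.6e-07), and not with an estimated correlation (adjusted p = 0.738). The estimate was 0.85, so the members moved together and the smaller p-value overstates the evidence. Of its members 17 were higher and 3 lower on both arrays. The neutrophil chemokine CXCL8 stood at 0.68 and 2.95 and the apoptosis inhibitor BIRC3 at −0.04 and 3.95. The vector RNA of array 2 stood apart for this list, its intensities lying at a median of −2.0 (log2) from the mean of both array 1 RNAs, against −0.78 for the IMP-3 RNA of array 2. BIRC3 had intensities of 11.67 (vector) and 11.63 (IMP-3) on array 1, and 7.04 and 10.98 on array 2. DNA replication genes had a median of −0.42 over 30 genes (−0.04 and −0.83). Camera called them lower at the preset correlation (adjusted p = 8.8e-07), and not with an estimated correlation (adjusted p = 0.738). That estimate was 1, so the same limit applies. Of these 20 were lower and 1 higher on both arrays, with the S phase cyclin CCNE2 at −0.09 and −1.51 and the licensing factor CDC6 at −0.17 and −1.27. Here too the vector RNA of array 2 stood apart, at a median of 0.98 from the array 1 mean, against 0.17 for IMP-3 RNA. Genes of the mitotic cell cycle stood at 0.33 on array 1 and −0.21 on array 2 (median 0.05, adjusted p = 0.273), with CENPF at 0.49 and 0.52 and CDK1 at −0.12 and −0.70. That list passed the test with median centring (median 0.37) and with scale normalisation (0.18), both at the preset correlation, and with loess alone it had adjusted p = 0.889 with an estimated correlation.

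In all, camera at the preset correlation called 16 of the 32 lists, 15 higher and 1 lower, and with an estimated correlation it called 0 (adjusted p = 0.738 for each of the 16). With an estimated correlation it had also called 0 of 20 simulated lists that were shifted, so its lack of calls is no evidence against a shift. At the preset correlation it had called 66 of 100 unshifted lists whose members shared a deviation, so its calls alone do not establish one. Fry called 0, with a smallest adjusted p of 0.268 for a shift in 1 direction and 0.553 for changes in either. No member of any list passed limma's threshold over all genes, and 1 member passed when adjusted over the list alone. Among 10000 random lists of matched intensity, the median of the DNA replication list lay at percentile 0, that of hypoxia and glycolysis genes at 89.35, that of ribosomal protein genes at 97.7 and those of the other called lists at 99.25 or above. Each of 7 called lists kept its call in all alternatives with a test, and 9 lost it in at least 1.

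Immediate early genes, which respond within minutes to growth signals, had a median of 0.54 (−0.09 on array 1 and 0.94 on array 2, adjusted p = 0.0022) and feedback genes of the MAPK pathway 0.32 (−0.05 and 0.68, adjusted p = 0.00278), with adjusted p = 0.738 with an estimated correlation for each, and both medians lay above 0 on array 2 alone. Of 22 immediate early genes 9 were higher and 2 lower on both arrays, with the zinc finger factor EGR1 at 0.10 and 3.15 and the matricellular CCN2 at 0.68 and 1.79. Vector RNA of array 2 lay at a median of −1.30 from the array 1 mean for these genes, and IMP-3 RNA at −0.46. EGR1 had intensities of 12.63 and 12.74 on array 1, and 9.42 (vector) and 12.58 (IMP-3) on array 2. Of 16 feedback genes 6 were higher and 1 lower, with SPRY1 at 0.51 and 1.24 and SPRY2 at 0.31 and 1.20, and vector RNA of array 2 lay at −0.43 from the array 1 mean, against −0.03 for IMP-3 RNA.

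Replication-dependent histone genes had nearly equal medians of 0.28 and 0.31 on the 2 arrays (0.35 for the mean ratio, adjusted p = 0.000196, and adjusted p = 0.738 with an estimated correlation). Of 13 measured, 10 were higher and 0 lower on both arrays, with H1-2 at 0.55 and 1.69 and H2BC11 at 0.28 and 0.73, though near-identical copies can share a probe. Of the array 2 RNAs the IMP-3 one lay farther from the array 1 mean here, at a median of 0.80 against 0.30 for vector, and vector was farther for 4 of 13 genes. Ribosomal protein genes had medians of 0.18 and 0.28 (0.18 for the mean ratio, adjusted p = 0.00116, and adjusted p = 0.738 with an estimated correlation). RPL5 stood at 0.21 and 0.88 (−0.15 and 0.21 at a second probe) and RPS3 at 0.47 and 0.57 (0.05 and 0.59 at a second probe). With the scanner's processed signals and with the deposited value table the ribosomal median was 0.04 and the call was lost.

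Pigmentation and melanocyte genes had a median of 0.16 (0.15 and 0.23, adjusted p = 0.00596, and adjusted p = 0.738 with an estimated correlation). Of 24, 10 were higher and 0 lower on both arrays, with the receptor genes KIT at 0.35 and 1.40 and EDNRB at 0.71 and 0.98. Markers of undifferentiated melanoma had a median of 0.24 (−0.03 and 0.48, adjusted p = 0.0676), with the receptor kinase AXL at −0.06 and 1.96. That list was called at the preset correlation with no pairing of the channels, and with the pairing it had adjusted p = 0.738 with an estimated correlation.

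Among matrix genes, extracellular proteases and their inhibitors had a median of 0.21 (0.05 and 0.38, adjusted p = 0.00278), collagens, laminins and matrix proteins 0.26 (0.04 and 0.37, adjusted p = 0.0368) and mesenchymal transition genes 0.33 (−0.0047 and 0.60, adjusted p = 0.0368), all with adjusted p = 0.738 with an estimated correlation. The metalloprotease inhibitor TIMP3 stood at 0.46 and 3.41, the plasminogen activator PLAT at 0.42 and 2.81, the proteoglycan DCN at 0.22 and 3.15 and TGFBI at 0.17 and 3.07. Of the proteases 13 of 28 were higher on both arrays and 2 lower, of the matrix genes 19 of 32 and 10, and of the mesenchymal genes 10 of 22 and 6. Fibroblast markers, of which 6 of 11 are also on the matrix list, had a median of 0.27 (0.07 and 0.42, adjusted p = 0.0368, and adjusted p = 0.738 with an estimated correlation). With median centring, which moved the median of all genes to 0.14, these 4 lists lost their calls at medians of 0.36 (proteases), 0.37 (matrix), 0.56 (mesenchymal) and 0.26 (fibroblast). Matrix and fibroblast lists also lost them with the filter on both channels, at medians of 0.20 and 0.27. With an intensity trend, which left the medians at 0.26 (matrix), 0.27 (fibroblast) and 0.33 (mesenchymal), these 3 lists lost their calls, and the mesenchymal list also lost its call with processed signals and the deposited value table (0.34 in each).

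Insulin-like growth factor genes had a median of 0.26 (−0.05 and 0.42, adjusted p = 0.0368) and cancer-testis antigens 0.19 (0.02 and 0.30, adjusted p = 0.0321), both with adjusted p = 0.738 with an estimated correlation. Both lost their calls with median centring, at medians of 0.48 and 0.38. The growth factor list also lost its call with processed signals and the deposited value table (0.35 in each), scale normalisation (0.19) and the mean of all probes (0.17). The binding protein IGFBP2 stood at −0.47 and −3.10, the imprinted RNA H19 at −0.13 and 2.42, MAGEC2 at 0.35 and 0.80 and PRAME at −0.05 and 1.08. Of 17 growth factor genes 6 were higher and 2 lower on both arrays, and of 16 cancer-testis genes 8 and 1.

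Genes of the unfolded protein and amino acid response had a median of 0.18 (0.10 and 0.20, adjusted p = 0.00444), cholesterol synthesis genes 0.21 (0.09 and 0.33, adjusted p = 0.00308) and hypoxia and glycolysis genes 0.07 (0.10 and 0.08, adjusted p = 0.0441), each with adjusted p = 0.738 with an estimated correlation. Of 26 stress response genes 12 were higher and 3 lower on both arrays. The transcription factor genes ATF3 and DDIT3 stood at 0.73 and 1.19 (0.32 and 0.56 at a dimmer ATF3 probe) and at 0.63 and 1.24. For the stress response genes the RNAs of array 2 lay at medians of −1.37 (vector) and −0.85 (IMP-3) from the array 1 mean. Of 24 cholesterol genes 11 were higher and 3 lower, and with no pairing of the channels that call was lost at the same median of 0.21. For this list the IMP-3 RNA of array 2 lay farther from the array 1 mean, at a median of 1.03 against 0.55 for vector RNA, and the vector RNA was the farther one for 4 of 24 genes. Of 30 hypoxia genes 13 were higher and 6 lower, with the glucose transporter SLC2A1 at 0.61 and 1.58 and adrenomedullin (ADM) at 0.73 and 1.11, and the median of the list lay at percentile 89.35 of the random lists. Its call was lost with processed signals and the deposited value table (median 0.056 in each), an intensity trend (0.072) and the mean of all probes (0.051).

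The remaining lists were not called. Heat shock genes had a median of −0.17 (adjusted p = 0.086, and adjusted p = 0.738 with an estimated correlation), with the small heat shock protein CRYAB at 0.62 and 2.83 and HSPA1A, which has a near-identical copy, at −0.53 and −2.72. At the preset correlation the list was called with the mean of all probes (median −0.31), an alternative chosen after seeing the data. The median was −0.11 for p53 targets (adjusted p = 0.206, SESN1 at −0.20 and −1.42 but 0.14 and −1.11 at a dimmer probe, BTG2 at 0.09 and −1.47) and −0.08 for RNA-binding partners (adjusted p = 0.772, PABPC1 at 0.07 and 0.87). It was 0.08 for interferon-stimulated genes (adjusted p = 0.206, IFITM1 at −0.38 and −1.61, OASL at 0.12 and 1.39) and 0.07 for oxidative phosphorylation (adjusted p = 0.411, UQCRC2 at 0.33 and 0.90, SDHD at −0.15 and −0.73). At the preset correlation the former was called with no pairing and the latter with median centring (median 0.55). Without these changes, they had adjusted p = 0.804 (interferon) and adjusted p = 0.738 (oxidative phosphorylation) with an estimated correlation. Antigen presentation genes had a median of 0.02 (adjusted p = 0.784), with HLA-DRA at −0.32 and 1.94 (IMP-3 channel well above background on 1 array) and HLA-DPB1 at −0.19 and −1.34, and camera gave them the lower direction. Epithelial adhesion genes had a median of 0.04 and a mean of −0.04 (adjusted p = 0.622), with the desmosomal DSP at −0.11 and −1.84. Among markers of other cell types the median was 0.12 for keratinocytes (adjusted p = 0.327, KRT17 at −0.01 and 0.83, its vector channel well above background on 1 array), 0.04 for leukocytes (adjusted p = 0.474, LAPTM5 at 0.04 and 0.39) and 0.09 for endothelium (adjusted p = 0.622). Nervous system markers had a median of 0.10 and a mean of −0.17 (adjusted p = 0.843, lower direction), with NEFM as above and NEFL at −0.21 and −4.21. The endothelial PECAM1 was not well above background in vector RNA on either array and stood at −0.04 on array 1 and 1.22 on array 2 (limma adjusted p = 0.683). The bound from its means over both arrays, at least 1.51-fold higher in IMP-3 cells, equals the fold of its mean ratio. It rests on array 2, and array 1 showed no rise.

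**Figure D3:**
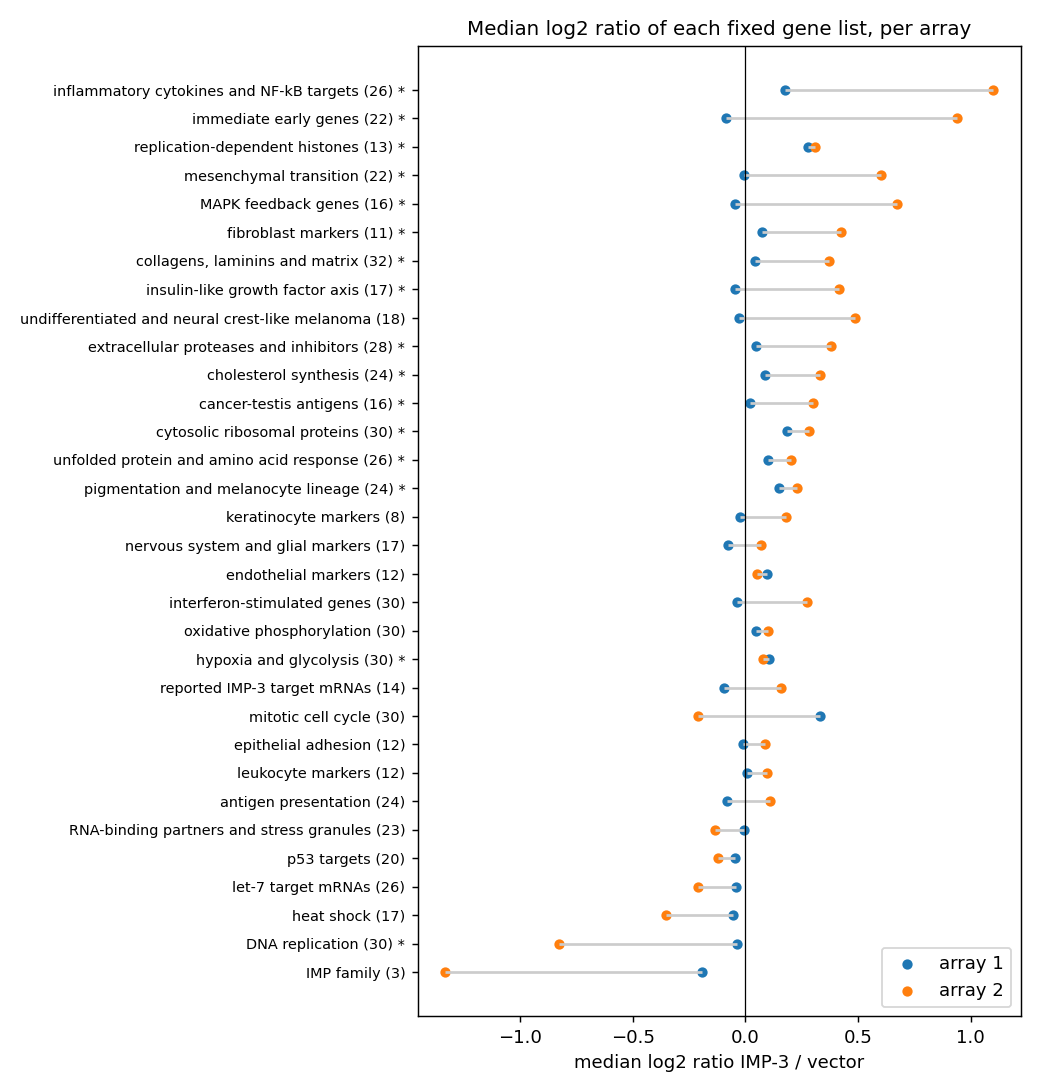
Median IMP-3 over vector log2 ratio (x axis) of each fixed gene list (y axis, with the number of genes measured) on array 1 (blue) and array 2 (orange), where an asterisk marks lists called by camera at the preset correlation. The inflammatory list lies at 0.17 and 1.1, the DNA replication list at −0.04 and −0.83, and the histone list at 0.28 and 0.31.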

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

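The mean of all kept probes per gene was the alternative chosen after seeing the data. In no alternative did a gene pass limma's adjusted p of 0.05. The smallest adjusted p was 0.142 with scale normalisation, 0.256 with median centring and 1.00 with no pairing of the channels (no replicate block), against 0.682. Of 1445 values recomputed, 1360 kept their direction and side of the threshold or stayed within their spread, 31 moved, 24 lost and 11 gained a call and 19 turned, and the cause was not tested except where stated. For a named gene on a single array this was fixed in advance, since with 2 arrays each value lies within the SD of their mean. As no gene passed in any alternative, named genes could change there only in direction. The 1360 is therefore no measure of how robust the single genes are. Genes with ratios of at least 2-fold on both arrays, 11 higher and 10 lower, numbered 48 and 55 with the scanner's processed signals, 48 and 56 with the deposited value table, 50 and 16 with median centring, and 28 and 16 with scale normalisation. The lower count was 16 with a normexp offset of 16. At 1.5-fold they numbered 63 and 43, since the limit is lower, and 138 and 157 by the scanner's own p on both arrays. On a single array they ranged from 11 to 577 higher and from 12 to 684 lower, where array 1 gave the smaller counts.

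Median centring moved the median of all genes to 0.14 and raised Spearman's rho between the arrays from 0.34 to 0.58. It turned IGF2BP2 to 0.18. Camera's direction turned for uncalled lists at medians that include that shift. These were 0.11 (epithelial adhesion), 0.18 (p53 targets), 0.19 (antigen presentation), 0.12 (heat shock), 0.27 (RNA-binding partners), 0.19 (keratinocyte), 0.13 (leukocyte) and −0.020 (endothelial). The medians of heat shock, keratinocyte and antigen presentation genes stayed on the same side of the median of all genes, so only camera's direction turned for them. The number of lists called lower was 2 in place of 1 with a normexp offset of 16, processed signals, scale normalisation, no pairing, the deposited value table and the mean of all probes. The reported IMP-3 targets turned direction at 0.087 with the filter on both channels, at 0.051 with an intensity trend and at 0.051 with no pairing. Nervous system markers turned at 0.10 in the latter 2 and antigen presentation at 0.022 with no pairing. Over single arrays the median ranged from −0.0047 to 0.603 for mesenchymal transition, from −0.0462 to 0.416 for the insulin-like growth factor axis, from −0.0872 to 0.941 for immediate early genes and from −0.0466 to 0.675 for MAPK feedback, with the negative values on array 1. IGF2BP3 ranged from −1.33 to −0.19 and HMGA2 from 1.09 to 2.06 over single arrays. Signal over background was lower on array 2, where 77.9% of probes were well above background in the vector channel.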

Other observations

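The tests of spike-in ratios, of pigmentation genes, of HMGA2 transcripts and of dye effects below were chosen after the ratios had been seen, and the genes of the first 2 paragraphs were chosen after their values were seen. Of 279 genes with ratios of at least 4-fold on array 2, 92 were higher and 187 lower in IMP-3 cells, and 133 of them lay within 0.25 (log2) of 0 on array 1. The neuronal intermediate filament INA stood at −0.07 on array 1 and −2.63 on array 2, the carbonic anhydrase CA2 at −0.09 and −3.37, and the Hedgehog transducer SMO at −0.09 and −2.88. On the other side the hair keratin KRT86 stood at 0.13 and 4.27, the urea transporter SLC14A1 at 0.13 and 3.59, the chemokine CCL2 at −0.12 and 3.30 and S100A4 at 0.20 and 2.80. For FDCSP, at 0.09 and 3.49, the vector RNA had log2 intensities of 13.19 on array 1 and 9.41 on array 2, against 13.28 and 12.90 for IMP-3 RNA. Although small, the array 1 ratio had the sign of the array 2 ratio for 249 of the 279 genes (89.2%), and the median of array 1 over array 2 log2 ratios was 0.10.

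The smallest unadjusted p of any probe (7.5e-05, limma adjusted p = 0.682) belonged to A_32_P167111, which has no gene name here. It lies on chromosome 3 at 177408943 to 177409002 (hg19) and stood at −4.16 and −3.72 on the 2 arrays (mean −3.94 ± 0.31, SD, n = 2).

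Ratios were wider on array 2 than on array 1 (SD 0.60 against 0.19), and if compressed dye ratios on array 1 were the reason, spike-in RNAs would show it, yet over 10 spike-ins the slope of array 2 on array 1 was 1.01 (SE 0.0129), which argues against that cause. Of 1258 reported genes at 2-fold or more on array 2, the vector RNA lay farther than the IMP-3 RNA from the array 1 mean in 67.6%, against 58.2% over all genes. Over all members, whatever their ratio, the share lay below 50% in 8 of the 32 lists. It ran from 16.7% for cholesterol synthesis, 27.8% for undifferentiated melanoma and 30.8% for histones to 93.3% for DNA replication. Members of any ratio enter these shares, so they do not show which wide ratios come from the vector RNA. A vector sample that stands apart on array 2 is a candidate explanation for only part of the genes, since the vector RNA was not the farther one in all. An untested difference between cultures or stable clones could set such a sample apart. RNA of another cell type in that sample would lower all melanocyte transcripts alike, and the upper quartile of pigmentation ratios on array 2 was 0.66, far from the 2 that the 92 higher genes need. For the 187 lower genes the pigmentation median on array 2 (0.23) would allow a share of 14.8% of other RNA in the vector sample, if the IMP-3 sample held none. Other RNA in both samples would cancel from the ratio at least in part, so this share does not bound it. The pigmentation median was above 0 on array 1 too (0.15), so the share is no sign of other RNA on array 2 in particular. With no profile of such cells here, other RNA cannot be told apart from a change within MeWo cells.

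The HMGA2 probes differed, with 1.09 and 2.06 in the 3′ UTR and −0.02 and 0.17 in the coding region. If low signal kept probes from wide ratios, 2-fold ratios would be few at the brightness of the coding probe. They were 1.24 times as frequent there as at the brightness of the UTR probe (7.26% against 5.86% on array 2). These shares cannot tell noise from true change, so whether this 1 probe responds to a change stays open. Distance from the 3′ end is not borne out as the sole cause. For comparison, 57 other transcripts had bright probes at least 1000 nt apart, the downstream one at least 2-fold changed on array 2. The pair with the largest downstream ratio in size was taken per transcript. The median of upstream over downstream log2 ratio on array 2 was 0.80 (quartiles 0.553 and 0.979). Of the 57, 2 were at or below the 0.0841 of HMGA2. Transcripts that differ in their 3′ part may account for the difference, and the 2 probes of HMGA2 on the array cannot decide it.

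All ratios come from 1 dye orientation. A fixed dye effect of each gene would, by itself, give equal ratios on both arrays. Over 20 of the genes with ratios of at least 2-fold on both, the median of array 2 over array 1 was 2.51, with 15 of the 20 above 1.5. This argues against a dye effect as the sole cause for the set. Ratios were wider on array 2 in general, so a dye effect as part of each ratio stays open for all of these genes. For 4 genes whose log2 ratios differed by under 0.5 between the arrays, ACTL8 and MAPK4 among them, it stays open also as the sole cause. Without a dye swap it cannot be told apart from an effect of the plasmid. The plasmid is the biological difference that the design names, and beside it the untested difference between cultures or stable clones stays open.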
